A study of Drosophila melanogaster with 8 samples.

How the data were processed

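RNA-seq was made from whole wing imaginal discs of Drosophila melanogaster larvae, the epithelial sacs that give rise to the wing and thorax and carry the adult muscle precursors (AMPs). Per the labels, larvae were kept at 29 °C and discs were dissected from wandering larvae at about 5 days after egg lay. RNA was purified with the Monarch miniprep kit and libraries were made with a ThruPLEX DNA-Seq kit, per the labels' protocols. The control crossed the driver line 1151 to w1118, and the other genotype, 1151>AntpCRISPR, targeted Antp with CRISPR under the same driver. Per the labels, each genotype has 4 libraries, here called wt 1 to wt 4 and CRISPR 1 to CRISPR 4. The labels mark CRISPR 1, CRISPR 2, wt 2 and wt 3 as used by the submitters and the other 4 as not used, with no reason given. Nothing in the labels says that libraries of a genotype came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical. The control cross carries no CRISPR transgene, so a difference in genetic background goes with genotype.

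The authors deposited raw read counts per gene, 1 table per library, and per the submitters' processing notes the reads went through FastQC, Trimmomatic 0.36, STAR and DESeq2 with the genome build dm6. The counting program, its strand setting and the annotation release are not given in the sources used here. Each table holds 17559 gene IDs and 5 special rows that name no gene, which stayed out of library sizes and tests. Of all reads in a table, those on no feature came to 0.955% to 1.91%, ambiguous reads to 3.07% to 3.44% and reads without a unique place to 2.22% to 4.40%. Symbols were matched for 17253 IDs, and 306 IDs have none here. Coordinates come from Ensembl's annotation of the same release 6 assembly. Where exons of different genes overlap, or near-identical gene copies exist, a gene's count is uncertain because the strand setting is unknown.

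Gene reads per library ranged from 35076546 in CRISPR 1 to 47980221 in wt 2, and 11588 to 13333 genes had at least 1 read. Before TMM factors, a count of 0 allows a level of up to 0.0625 to 0.0855 CPM (counts scaled to a common library size), taking 3 counts as the floor. On the TMM scale of the levels below, each bound is divided by its library's factor, from 0.898 (wt 1) to 1.05 (wt 3). Floors cover counting error only, since PCR copies cannot be told from separate molecules. Levels are CPM scaled by TMM factors over the 8 libraries, and group values are means ± SD over libraries.

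The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, and the two-sided quasi-likelihood test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p for a gene is from edgeR unless DESeq2 or limma is named. The fits compared genotypes among the 4 used libraries and among all 8, tested whether the genotype effect differed by use status (an interaction term), and compared not-used with used libraries at a fixed genotype. Antp was also compared by an exact permutation test of log2 CPM, whose smallest possible p with 4 libraries per group is 0.0286, and, chosen after seeing the data, by an exact sign-flip test over same-numbered pairs. The other tools were DESeq2 1.42.0 and limma 3.58.1, and figures were drawn in Python 3.11.15.

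The 27 lists name Hox genes, AMP and muscle genes, wing disc epithelium, signalling pathways, growth, stress and stage, and markers of tissues that a dissection could carry over. Of 628 entries, 594 matched a gene ID, and lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, where fry asks whether a list's genes move on balance one way, or in either direction (mixed), without comparing them with other genes.

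Named genes follow a rule: Antp and the tested members of the Hox list, the called genes with the largest rise and fall and an average log2 CPM of at least 1 in each genotype comparison, and the members of each list with the smallest p whether or not they passed. For the genes with the largest rise and fall, every CRISPR library also had to lie on one side of every wt library in that comparison. Their separation there follows from the rule and is no result. Where no gene passed, as for the interaction and use status, genes with the smallest p stand in. The text gives a selection of these, and genes outside the rule are said to be so.

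The wt 2 and wt 3 libraries were closer to each other than any other pair. Over genes with at least 400 reads in a pair, the robust SD of their log2 ratio was 0.0592, against 0.0418 from counting alone and 0.148 to 0.500 in the other 27 pairs. Their chi-square per degree of freedom, 7.83, was above sampling noise, which separate preparations of a single RNA would also be. The labels list them as 2 libraries and they were counted so, but whether they are separate samples is not known, and if not, n and SD for the used wt libraries describe preparation only. Their sum was tried as 1 library.

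Replicate numbers are shared by the genotypes. Over 9255 genes, deviations from the genotype mean correlated at 0.108 to 0.800 between libraries of the same number (mean 0.458) and at a mean of -0.149 between different numbers, and 3 of 4 libraries in each genotype were closest to their own number. Number 2 was the exception, with 0.108 between wt 2 and CRISPR 2, while CRISPR 2 was closer to wt 1 (0.380) and wt 2 to CRISPR 3 (0.459). Deviations cancel within a genotype, so positive values for the same number make the others negative. The pairing comes from the data, by the bound of 0.1 set for every pair, which number 2 barely clears. Number 3 is not distinct either, since CRISPR 3 correlated at 0.462 with wt 3 and at 0.459 with the closely similar wt 2. In the SD of log2 ratios, wt 1 lay nearer to CRISPR 2 (0.230) than to CRISPR 1 (0.250). By that SD CRISPR 2 lay nearest to wt 2 among the wt libraries (0.203), and number 4 gave 0.148. How far numbers 1 to 3 pair the libraries is therefore uncertain. A fit with the number as a block was made for all 8 libraries. The used libraries of the genotypes share only number 2.

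On simulated counts with 200 changed genes, the fit to the used libraries recovered 40% of 1.5-fold, 90% of 2-fold, 98% of 4-fold and 100% of 8-fold changes over 9711 genes, with 17 false calls among 181. The fit to all 8 recovered 8%, 60%, 92% and 98% over 9255 genes, with 4 false calls among 133. The changed genes were drawn only from those with an average log2 CPM above 1. Simulated libraries were independent, with the same spread in both genotypes and neither pairing nor carried-over tissue. The real libraries differ from this, so the rates may be too favourable for them.

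Alternatives changed the scaling, the filter, the tool, the threshold and the libraries in the fit, added use status or the block, and left out each library in turn. Further fits chosen after seeing the data took the spread over all 8 libraries for the genes tested among the used ones, added the block to the interaction, summed wt 2 and wt 3, exchanged used for not-used libraries, and left out libraries that stood apart.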

Results

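Gene expression was measured by RNA-seq in whole wing discs of wandering third-stage larvae, in 4 control libraries (wt, the driver line 1151 crossed to w1118) and 4 libraries in which the same driver directed CRISPR against Antp (CRISPR). The series asks what Antp, a Hox transcription factor that specifies thoracic segments, regulates in the adult muscle precursors (AMPs), the progenitors of flight muscle that lie on the disc epithelium. Each disc holds both cell types, and the counts do not separate them. Depth ranged from 35076546 gene reads in CRISPR 1 to 47980221 in wt 2. The labels mark 2 libraries of each genotype as used by the submitters (CRISPR 1, CRISPR 2, wt 2 and wt 3), so each genotype comparison was made among these 4 and among all 8.

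The libraries differed in ways that genotype does not describe. Transcripts of midgut digestive enzymes and other larval tissue, taken over the 9 members detected, summed to 1440 CPM in wt 2, 1454 CPM in wt 3 and 751 CPM in CRISPR 3, but to between 3.92 CPM (wt 4) and 12.9 CPM (CRISPR 2) in the other 5 libraries. Sarcomere genes were highest in CRISPR 2, with a mean log2 CPM of 6.31 against 3.73 (CRISPR 3) to 5.18 (wt 3) elsewhere. In wt 4 and CRISPR 4, longer transcripts were lower relative to the median library (Spearman's rho across genes -0.40 and -0.49), while the other 6 libraries lay between -0.071 and 0.26. Genes are not independent replicates, so no p is given for these correlations. The first principal component, with 38.1% of the variance, had wt 4 and CRISPR 4 at one end, and the second (31.0%) had wt 2, wt 3 and CRISPR 3 together at its negative end.

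Antp itself (FBgn0260642, 3R 6896253 to 6999228, dm6 coordinates, sharing exonic sequence with CG46458) was measured in every library with 5452 to 7812 reads. Its level was 195 CPM in wt 1, 137 CPM in wt 2, 140 CPM in wt 3 and 121 CPM in wt 4, and 211, 166, 145 and 148 CPM in CRISPR 1 to CRISPR 4. The means were 148 ± 32.3 CPM in wt and 167 ± 30.3 CPM in CRISPR (SD, n = 4 each). The log2 difference of 0.18 gave p = 0.343 in a two-sided exact permutation test over 35 splits, which ignores the pairing of libraries by number. Antp was higher in CRISPR in 4 of 4 numbered pairs, where an exact sign-flip permutation test over pairs gives p = 0.125, the smallest it can give. The edgeR fit with the number as a block gave an adjusted p of 0.560 (0.0311 unadjusted). Among the used libraries edgeR gave a log2 change of 0.40 (SE 0.11, adjusted p = 0.135) for Antp, and DESeq2 0.41 with an adjusted p of 0.0342. Among the not-used libraries the log2 change was -0.11. Without CRISPR 1 the edgeR value for the used libraries was 0.25 (adjusted p = 5.8e-10), and without CRISPR 2 it was 0.55 (adjusted p = 4.5e-46), fits in which the lone CRISPR library was assumed to vary as little as wt 2 and wt 3 did. CRISPR can break a gene without lowering its RNA, and cells outside the AMPs also contribute Antp reads, so this level gives no check of the genotype labels.

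**Figure D1:**
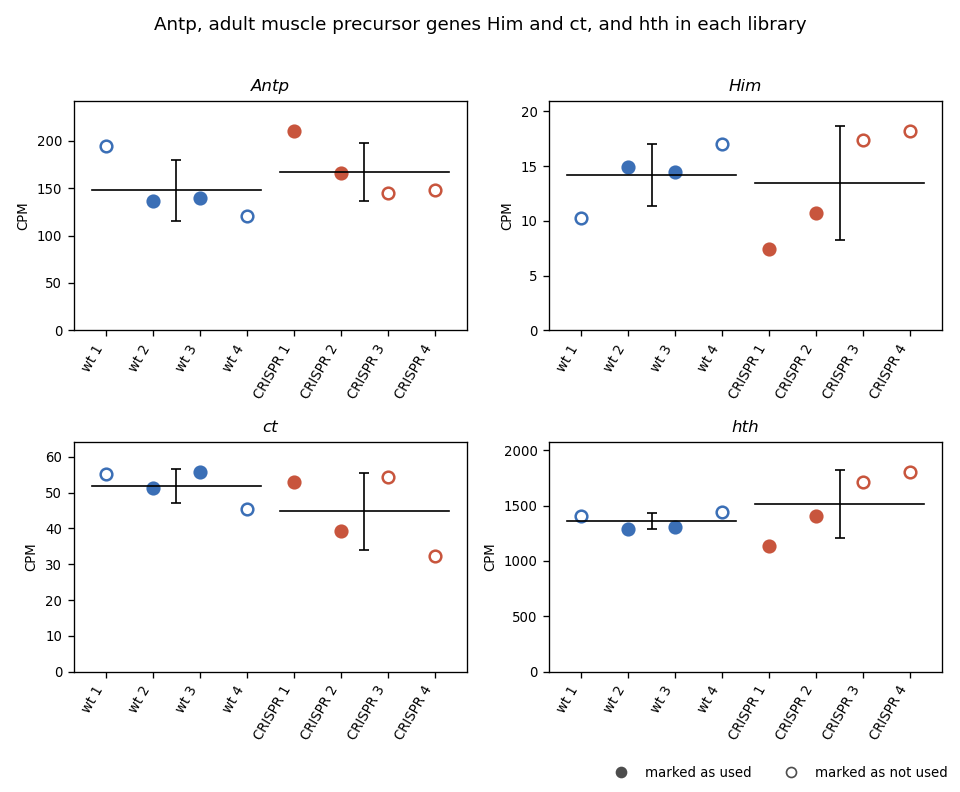
Levels of Antp and of the AMP-associated genes Him, ct and hth in CPM (linear axis from 0) in each of the 8 libraries, blue for wt and red for CRISPR, with filled points for libraries marked as used, open points for the others, and lines at the mean ± SD over 4 libraries. The genotypes overlap in all 4 genes, and Antp averages 148 CPM in wt and 167 CPM in CRISPR.

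The first comparison asked which genes differed between genotypes among the 4 used libraries. The genes that fell from wt 2 and wt 3 to CRISPR 1 and CRISPR 2 included transcripts of larval gut, fat body and nervous system (n = 2 libraries each throughout this comparison). Jon65Aiv (FBgn0250815, 3L 6039155 to 6040135), a digestive serine protease, fell from 1275 ± 10.5 to 2.93 ± 2.43 CPM, 431-fold (SE 0.61 on the log2 scale, adjusted p = 0.0113), where the log2 change of -8.75 became -10.09 without CRISPR 2 and -8.11 without CRISPR 1. Fbp1 (FBgn0000639, 3L 14094589 to 14098053), the fat body receptor for storage proteins, fell from 82.8 ± 1.77 to 2.91 ± 0.166 CPM, 29.3-fold (SE 0.082, adjusted p = 1.7e-04). The synaptic active zone gene brp (FBgn0259246, 2R 9503765 to 9541565) fell from 2.13 ± 0.177 to 0.0566 ± 0.00823 CPM, 37.1-fold, where the CRISPR value rests on 4 reads (SE 0.39, adjusted p = 0.0120). In all, edgeR called 264 of 9711 genes, of which 37 rose and 227 fell, and 164 of those that fell did so at least 8-fold.

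**Figure D2:**
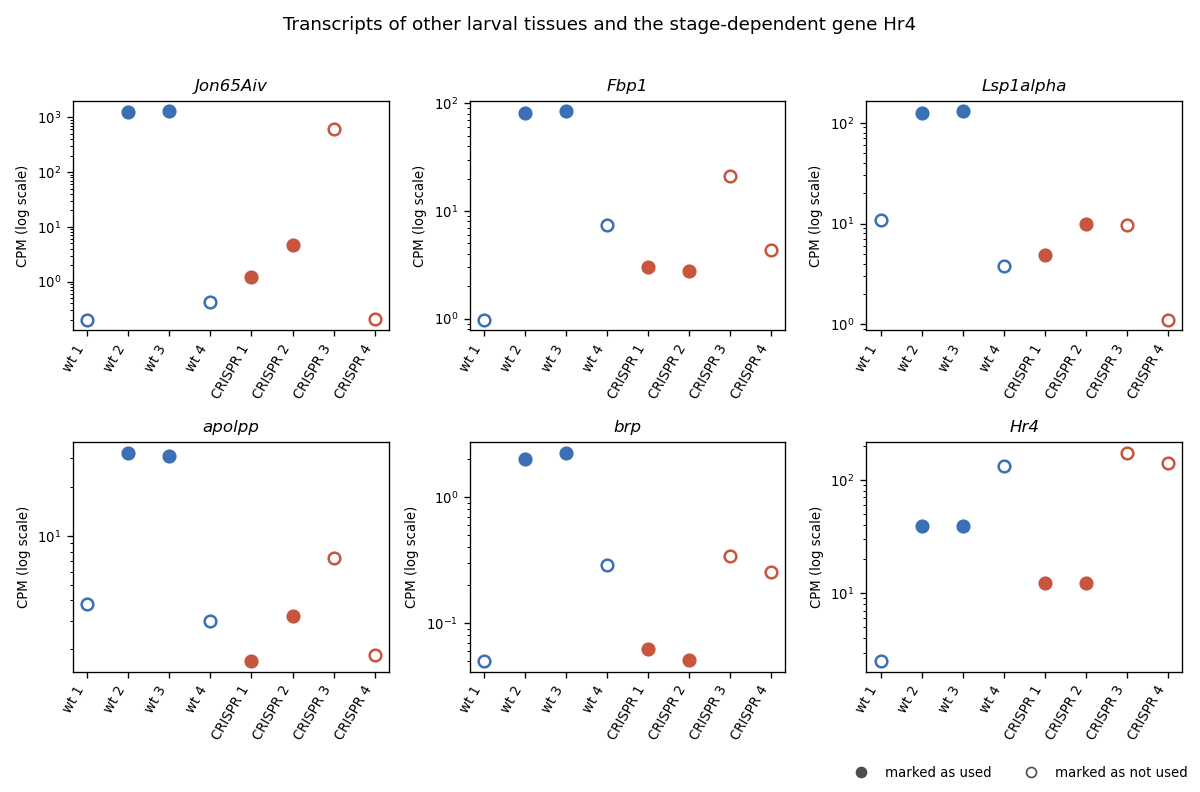
Levels of the gut protease Jon65Aiv, the fat body genes Fbp1, Lsp1alpha and apolpp, the synaptic gene brp and the ecdysone-response gene Hr4 in CPM (log axis) in each of the 8 libraries, blue for wt and red for CRISPR, filled for libraries marked as used and open for the others. Jon65Aiv lies at 1267 CPM in wt 2, 1282 CPM in wt 3 and 613 CPM in CRISPR 3, and at 4.65 CPM or less in the other 5 libraries.

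Of the fixed lists, fat body and gut held the most called members. In the fat body list 7 of 16 tested members fell (13 fell and 1 rose adjusted over the list alone), with a median log2 change of -2.50. Besides Fbp1, Lsp1alpha, a larval serum storage protein, fell 17.5-fold (127 ± 3.41 to 7.39 ± 3.60 CPM, adjusted p = 0.0193, with a log2 change of -4.13 that became -4.77 without CRISPR 2), and the lipid carrier apolpp (overlapping Zyx) fell 13.2-fold (31.8 ± 1.06 to 2.44 ± 1.07 CPM, adjusted p = 0.0193). The fat body list passed camera (adjusted p = 2.7e-13), with adjusted p = 0.456 with an estimated correlation. In the gut list 5 of 9 members fell (5 adjusted over the list alone), with a median log2 change of -6.09. Among them were the proteases Jon25Bi, from 124 ± 0.634 to 0.530 ± 0.616 CPM (adjusted p = 0.0116), and alphaTry, from 21.8 ± 0.989 to 0.0254 ± 0.0359 CPM (2 reads, adjusted p = 0.00371). Leaving out CRISPR 2 or CRISPR 1 moved the log2 change of Jon25Bi from -7.80 to -10.38 (3 reads left in CRISPR 1) or -7.01. Without CRISPR 1 that of alphaTry moved from -9.50 to -8.68, on the 2 reads in CRISPR 2, and without CRISPR 2 it has no measured value, as CRISPR 1 had 0 reads. These proteases have close paralogs, so the share of each is uncertain. The gut list passed camera at 2.2e-08, with adjusted p = 0.456 with an estimated correlation. In the nervous system list 3 of 18 members fell, namely brp, the GABA receptor Rdl and complexin (cpx), and adjusted over the list alone 10 fell and 1 rose. Its camera adjusted p was 4.9e-06, with adjusted p = 0.456 with an estimated correlation. In the proneural list 2 of 23 members fell (5 adjusted over the list alone), the neural transcription factors pros (overlapping lncRNA:CR46008), 24.6-fold, and scrt, 16.1-fold (camera adjusted p = 0.00131, with adjusted p = 0.456 with an estimated correlation). Outside this comparison, Jon65Aiv stood at 613 CPM in CRISPR 3, 0.20 CPM in wt 1 and 0.421 CPM in wt 4.

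The deepest falls outside the lists were in uncharacterised genes. CG14332 (FBgn0038509, 3R 17421690 to 17422202) stood at 87.7 ± 2.14 CPM in the used wt libraries and had 0 reads in CRISPR 1 and CRISPR 2, at least 2086-fold lower against a floor of 3 counts over the pair. By the same floor CG42834 was at least 1778-fold lower (74.7 ± 2.94 CPM in wt) and CG8661 at least 482-fold lower (20.2 ± 0.603 CPM in wt). CG14332 and CG42834 also had 0 reads in wt 1, while in wt 4 they stood at 3.72 and 4.01 CPM. CG7465 fell from 113 ± 0.389 to 0.0439 ± 0.0262 CPM (3 reads, adjusted p = 1.3e-04), and CG17145 from 106 ± 1.99 to 0.0791 ± 0.0677 CPM (adjusted p = 5.4e-04). The log2 change of CG7465 moved from -11.33 to -11.98 without CRISPR 1, and that of CG17145 from -10.29 to -11.66 without CRISPR 2 and -9.69 without CRISPR 1. The values -11.98 and -11.66 each rest on 1 read in the CRISPR library that was left.

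Among growth genes 1 passed. In the proliferation list 0 of 25 members passed in edgeR over all genes (16 at an unadjusted p under 0.05, 9 in DESeq2 and 2 in limma-voom), and 16 rose adjusted over the list alone. The list's median log2 change was 0.22 (camera adjusted p = 4.1e-08, with adjusted p = 0.456 with an estimated correlation). The mitotic phosphatase gene stg had a log2 change of 0.47 (SE 0.076, adjusted p = 0.0627), and the cytokinesis kinesin gene pav had 0.39 (SE 0.061, adjusted p = 0.0591), neither of which passed. In the ribosome biogenesis list 1 of 16 members rose over all genes and 7 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 4.9e-06, with adjusted p = 0.571 with an estimated correlation). That member was Polr1A (FBgn0019938, overlapping CG12869), encoding the large subunit of RNA polymerase I, which rose from 159 ± 3.23 to 215 ± 2.15 CPM (adjusted p = 0.0483). The highest mean log2 CPM of both lists was in wt 1, a library outside this comparison (7.54 for proliferation and 7.85 for ribosome biogenesis, against 7.50 and 7.59 in CRISPR 1), and over all 8 libraries the medians were 0.053 and 0.042.

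In the sarcomere list 1 of 26 members rose, also adjusted over the list alone, and the median log2 change was 0.84 (camera adjusted p = 0.0141, with adjusted p = 0.765 with an estimated correlation). The mean log2 CPM of the list was 6.31 in CRISPR 2 and 4.59 in CRISPR 1, which lay below wt 2 (5.15) and wt 3 (5.18). The member that rose was Strn-Mlck (FBgn0265045, a titin-related muscle kinase gene overlapping Cyp4aa1), from 10.4 ± 0.657 to 21.7 ± 2.53 CPM (log2 1.03, SE 0.14, adjusted p = 0.0453), and its log2 change was 0.89 without CRISPR 2.

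For the AMPs, 0 of 19 tested identity and progenitor genes passed in edgeR (3 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom), and 0 passed adjusted over the list alone. Their median log2 change was -0.21, and camera gave an adjusted p of 0.295. The progenitor gene Him, an inhibitor of muscle differentiation, stood at 14.7 ± 0.364 CPM in wt and 9.10 ± 2.32 CPM in CRISPR (log2 -0.72, SE 0.22, adjusted p = 0.156). The Notch target E(spl)mgamma-HLH stood at 10.7 ± 0.738 and 15.2 ± 1.41 CPM (log2 0.47, adjusted p = 0.150). Myoblast fusion genes had 0 of 18 members called by edgeR (1 at an unadjusted p under 0.05, and 0 in DESeq2 and in limma-voom, camera adjusted p = 0.551). Flight and leg muscle regulators had 0 of 21 (3 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom), with 1 fall adjusted over the list alone (camera adjusted p = 0.0749). For these regulators fry gave adjusted p = 0.0374 (down) and 0.0144 (mixed). The fry values were 0.190 (down) and 0.0450 (mixed) for the AMP list, and 0.958 (up) and 0.224 (mixed) for fusion genes. Among the regulators lms, a homeodomain factor of direct flight muscle, had a log2 change of -1.39 (1.77 ± 0.0358 to 0.688 ± 0.177 CPM, adjusted p = 0.109).

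Of the Hox genes and their cofactors, 0 of 9 passed in edgeR over all genes (3 at an unadjusted p under 0.05, 3 in DESeq2 and 0 in limma-voom). Adjusted over the list alone, Antp rose and Scr and Ubx fell. Scr, at 3.34 ± 0.697 CPM in wt and 0.833 ± 0.280 CPM in CRISPR, had a log2 change of -2.06 (adjusted p = 0.0692 over all genes), and Ubx (overlapping asRNA:PS4), at 36.6 ± 0.964 and 22.2 ± 4.70 CPM, of -0.76 (adjusted p = 0.110). The cofactors exd (log2 0.27) and hth (-0.071), the related factors tsh (-0.025) and tio (-0.075), and the low-level lab (-0.32) and abd-A (-0.64) had adjusted p-values from 0.275 to 0.869. The list's camera adjusted p was 0.535.

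Ecdysone response and stage genes went both ways. Of 25 members 1 rose and 2 fell (2 and 8 adjusted over the list alone), and the median log2 change was -0.40 (camera adjusted p = 0.0344, with adjusted p = 0.477 with an estimated correlation). The nuclear receptor gene Hr4 (FBgn0264562, overlapping PIG-K) fell from 39.2 ± 0.0610 to 12.4 ± 0.0392 CPM (log2 -1.70, SE 0.082, adjusted p = 0.00411), and EcR, the ecdysone receptor gene, rose from 218 ± 9.26 to 322 ± 7.49 CPM (log2 0.52, adjusted p = 0.0343). The other member that fell was Fbp1, which the fat body list also holds. Across the not-used libraries Hr4 ranged from 2.52 CPM in wt 1 to 174 CPM in CRISPR 3. With CRISPR 3 and CRISPR 4 in place of CRISPR 1 and CRISPR 2, the log2 change was 2.01 for Hr4 and -0.39 for EcR.

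Among the genes that rose, sordd2 had 1 read over wt 2 and wt 3 and stood at 7.51 ± 6.02 CPM in CRISPR 1 and CRISPR 2 (adjusted p = 0.0405). Its log2 change of 9.07, which depends on that single read, was 7.93 without CRISPR 1, 9.72 without CRISPR 2 and 8.29 without wt 3, and it has no measured value without wt 2, as wt 3 had 0 reads. Without wt 2, as without wt 3, the call was lost (adjusted p = 0.163 and 0.187). CG7173 (FBgn0037099, 3L 21555373 to 21558226) rose from 0.604 ± 0.111 to 4.95 ± 0.153 CPM (log2 2.98, SE 0.26, adjusted p = 0.0193), and CG12592 (FBgn0037811, 3R 10338342 to 10340872) from 1.01 ± 0.0266 to 5.02 ± 0.875 CPM (log2 2.28, adjusted p = 0.0308). The glycerophosphate oxidase gene Gpo1 rose 5.24-fold, the glutathione S-transferase genes GstT3 and GstE1 rose 3.01-fold and 3.51-fold, and CG3777, which overlaps ewg, rose 2.09-fold, all with adjusted p-values from 0.00468 to 0.0374. GstE1 overlaps GstE10. In the heat shock list Hsp70Ba rose from 5.23 ± 0.0463 to 93.6 ± 55.8 CPM (adjusted p = 0.0319, log2 4.11 and 3.36 without CRISPR 1), a gene with near-identical copies, so its count is uncertain. Among wing epithelium markers 1 of 37 rose, also adjusted over the list alone (camera adjusted p = 0.528). This was zfh2 (overlapping Tdg), a transcription factor gene of the proximal wing, from 510 ± 4.70 to 970 ± 28.5 CPM (log2 0.89, SE 0.068, adjusted p = 0.0137). LamC, encoding a nuclear lamin, rose 1.68-fold (adjusted p = 0.0393), but its log2 change was -1.04 with CRISPR 3 and CRISPR 4 in the CRISPR arm.

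Of the remaining lists, salivary gland (0 of 10 members in edgeR, with 2 at an unadjusted p under 0.05, 1 in DESeq2 and 1 in limma-voom) and other discs (1 of 17 fell) passed camera with adjusted p-values of 0.0173 and 0.0317, each with adjusted p = 0.640 with an estimated correlation. Adjusted over the list alone, 1 salivary gland gene fell, and 6 genes of other discs fell and 1 rose. In the extracellular matrix and adhesion list 2 of 28 members fell (3 adjusted over the list alone), 1 of them CadN, the N-cadherin gene, by 0.59 on the log2 scale (adjusted p = 0.0252). In the detoxification list 1 of 14 members rose and 2 fell (2 and 4 adjusted over the list alone), and in the signalling list (FGF, EGF and Wnt) 1 of 29 fell (1 rose and 3 fell adjusted over the list alone). The lists for Notch targets, tracheal cells, hemocytes, DNA damage, immune response, sex determination, cuticle, heat shock, detoxification, signalling and adhesion had camera adjusted p-values from 0.0749 (hemocytes) to 0.783 (heat shock). In all, 10 of 26 tested lists passed camera with the preset correlation and 0 with an estimated one, where fry found 8 lists moving on balance one way and 19 with changes in either direction.

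The number of calls depended on the small spread of this set of 4. The residual biological coefficient of variation was 15.3%, against 30.3% over all 8 libraries, and with the spread taken over all 8 libraries the same contrast called 5 of the same 9711 genes (940 at an unadjusted p under 0.05, a fit chosen after seeing the data). With the filter over all 8 libraries as well, which left 9255 genes and 162 of the 264, it called 4. With wt 1 and wt 4 as the controls for CRISPR 1 and CRISPR 2, edgeR called 0 genes (224 at an unadjusted p under 0.05, chosen as a fit after seeing the data), and leaving out 1 library gave 39 (without wt 2) to 5759 calls (without CRISPR 2). Without wt 2, and equally without wt 3, 20 of the 31 called genes followed by name lost their call, all that rose among them, and 11 kept it. With wt 2 and wt 3 summed into 1 library, also chosen after seeing the data, edgeR called 40 genes, all of which fell. DESeq2 called 787 genes, of which 231 rose and 556 fell.

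The second comparison used all 8 libraries (n = 4 per genotype) and called 17 of 9255 genes, of which 6 rose and 11 fell (398 at an unadjusted p under 0.05). CG7173 rose from 0.507 ± 0.129 to 6.05 ± 1.37 CPM (log2 3.57, SE 0.28, adjusted p = 0.00405), and CG12592 from 0.971 ± 0.156 to 4.39 ± 0.938 CPM (log2 2.17, SE 0.25, adjusted p = 0.0227). The X-linked gene sordd2 (FBgn0052581, X 15796908 to 15799162) had at most 1 read in any wt library and 4.74 ± 4.75 CPM in CRISPR (log2 8.40, SE 1.02, adjusted p = 0.0308, and log2 7.42 without CRISPR 1). Antdh (FBgn0026268, X 11168030 to 11169058), an alcohol dehydrogenase-related gene, fell from 6.99 ± 3.37 to 0.0448 ± 0.0459 CPM (log2 -7.09, SE 0.64, adjusted p = 0.00613, and log2 -7.93 on 3 reads without CRISPR 3).

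Smaller changes of well expressed genes separated the genotypes as cleanly. Tektin-C (FBgn0035638, 3L 5794405 to 5796543), a gene for a filament protein of cilia and flagella, fell from 93.5 ± 12.7 to 41.6 ± 6.51 CPM (log2 -1.17, SE 0.15, adjusted p = 0.0391). The gene tut (FBgn0052364, 3L 8209577 to 8210743) fell from 33.2 ± 3.22 to 16.4 ± 2.78 CPM (log2 -1.02, adjusted p = 0.0410), and Adk3 (FBgn0026602, 2R 7243024 to 7245776), an adenylate kinase gene, from 58.6 ± 2.36 to 32.7 ± 4.26 CPM (log2 -0.84, adjusted p = 0.0410). CG6701 (FBgn0033889, 2R 13972984 to 13980165) fell from 160 ± 6.46 to 107 ± 5.41 CPM (log2 -0.57, SE 0.085, adjusted p = 0.0425). All 17 called genes separated the 4 CRISPR from the 4 wt libraries, which chance gives for 2.86% of genes in general, but these genes were chosen on the same 8 libraries, so the count is no independent evidence. In 10 of the 17 the lower genotype averaged under 0.20 CPM. Of the 8 called genes with values here, only CG7173 kept its call in each of the 8 fits that left out 1 library.

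**Figure D3:**
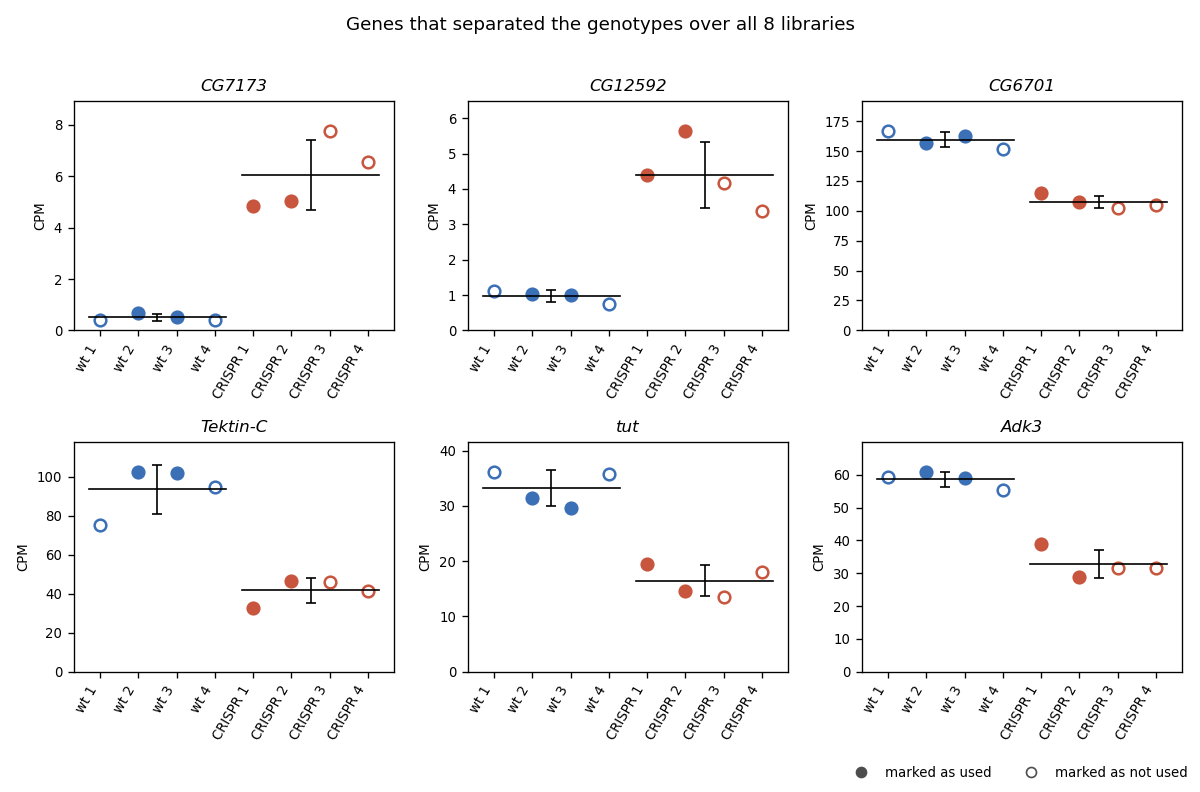
Levels of CG7173, CG12592, CG6701, Tektin-C, tut and Adk3 in CPM (linear axis from 0) in each of the 8 libraries, blue for wt and red for CRISPR, filled for libraries marked as used and open for the others, with lines at the mean ± SD over 4 libraries. In each of the 6 genes all CRISPR libraries lie on one side of all wt libraries, which the rule for named genes required.

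The other 9 called genes, outside the rule for named genes and listed after their values were seen, were CG30054, CG14982 and CR44383, which rose, and lncRNA:CR44185, lncRNA:CR44186, CG42364, CG10257, Dscam3 and antr, which fell. CG42364 and CG10257 share exons with other genes, so their counts are uncertain. CR44383 lies beside sordd2 on X, and lncRNA:CR44185 lies beside lncRNA:CR44186 on 2L. With the replicate number as a block only CR44383 and lncRNA:CR44185 of these 9 were still called. The other 7 had adjusted p-values from 0.130 to 0.253, with log2 changes that moved by at most 0.24 (Dscam3).

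Among the lists, 0 members of any list were called by edgeR over all 8 libraries. Fat body genes (7 of 14 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom and 0 adjusted over the list alone) had a median log2 change of -1.96 (camera adjusted p = 4.4e-07, with adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone, 7 of 13 fat body genes fell without the 1 gene that another list also holds, and 5 of 14 with the replicate number as a block. With use status as a term 0 did, with or without that gene. Nervous system genes (3 of 14 at an unadjusted p under 0.05, 0 in DESeq2, in limma-voom and adjusted over the list alone) had a median of -0.26 (camera adjusted p = 0.0133, with adjusted p = 0.425 with an estimated correlation). The mean log2 CPM of the fat body list was 4.34 in wt 2, 4.39 in wt 3, 3.02 in CRISPR 3 and 2.06 to 2.65 in the other 5 libraries, and that of the nervous system list was 2.68 in wt 2, 2.63 in wt 3 and 1.67 to 1.93 in the other 6. Summed levels differed from this. Nervous system sums were 1435 CPM in wt 1, 1127 in CRISPR 2, 1011 in wt 2, 1007 in CRISPR 1 and 991 in wt 3. They were 855 CPM in CRISPR 3, 710 in CRISPR 4 and 709 in wt 4. Fat body sums were highest in wt 2 (1039 CPM) and wt 3 (1065 CPM), but CRISPR 3 (590 CPM) did not exceed CRISPR 1 (591 CPM). No other list passed camera as fixed, and fry passed 0 lists. Without genes that other lists also hold, the 7 remaining flight and leg muscle regulators passed camera with a median log2 change of -0.28 (adjusted p = 0.00263, with 0.440 with an estimated correlation), and also with use status as a term (0.00525, with 0.375 with an estimated correlation) or with the block (0.0286, with 0.853). With the replicate number as a block camera passed 5 lists, adding hemocytes (adjusted p = 0.00993), salivary gland (0.0230) and extracellular matrix (0.0363), which with an estimated correlation had 0.762, 0.894 and 0.762. The AMP list (18 tested, 0 at an unadjusted p under 0.05 and 0 in DESeq2 and in limma-voom) had a median of -0.016 and a camera adjusted p of 0.570, where ct, a factor of direct flight muscle precursors, had a log2 change of -0.22 (51.9 ± 4.77 to 44.8 ± 10.7 CPM, adjusted p = 1.0). The sarcomere list had a median of 0.23 and a mean of 0.21, while camera gave its direction as down (adjusted p = 0.570). In the other-discs list the median was 0.15 and the mean -0.067, with camera down (adjusted p = 0.844).

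Genes that did not pass over all 8 libraries included Hsp70Ba (log2 3.70, adjusted p = 0.143, with y the only genes to pass adjusted over their lists alone with the lists as fixed and without the block), Eip75B, an ecdysone-induced nuclear receptor gene (log2 0.44, SE 0.11, adjusted p = 0.459), lms (log2 -1.75, adjusted p = 0.420) and the cuticle pigment gene y (log2 4.29, adjusted p = 0.299). GstT3 had a log2 change of 1.52 with an adjusted p of 0.143, and 0.0363 with the replicate number as a block. The number of called genes depended on single libraries, since leaving out 1 gave from 1 call (without CRISPR 2) to 26 (without CRISPR 1). Fits chosen after seeing the data, which left out wt 2, wt 3 and CRISPR 3, or wt 4 and CRISPR 4, called 0 genes in edgeR (123 and 433 at an unadjusted p under 0.05).

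Whether the genotype effect was alike in used and not-used libraries was asked next. The 2 sets share no library, but numbers 1 and 3 have a library in each, with opposite signs. Across 9044 genes fitted in both, the log2 changes had a Pearson correlation of 0.041 and a Spearman correlation of -0.24, as a description across genes. On log2 CPM with an offset of 0.5 the Pearson correlation was -0.13, where the pairing by number alone gives -0.32 with no genotype effect, so these correlations do not show that the effect differed. Of 151 genes called among the used libraries that were also fitted in the others, 56 (37.1%) had the same direction there, namely 13 of 37 that rose and 43 of 114 that fell, and 1 was called in both. The pairing, as far as it holds, lowers this share too. The not-used libraries alone gave 8 calls (7 rose and 1 fell). For the difference itself, edgeR's interaction test called 0 of 9255 genes (611 at an unadjusted p under 0.05, and 0 and 235 with the replicate number as a block, chosen after seeing the data), while DESeq2 called 151 and edgeR with no filter on low counts called 67. The smallest p-values in edgeR belonged to CREG, with a log2 difference of 2.94 (SE 0.31, adjusted p = 0.194), the sterol carrier gene Npc2b (2.82, adjusted p = 0.371) and CG11370 (-1.63, adjusted p = 0.371), none of which passed. CREG stood at 49.9 and 53.5 CPM in wt 2 and wt 3 and at 6.25 to 13.3 CPM in the other 6 libraries. With library size alone as the scaling, the median of all genes in this test moved from -0.052 to 0.14 on the log2 scale.

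**Figure D4:**
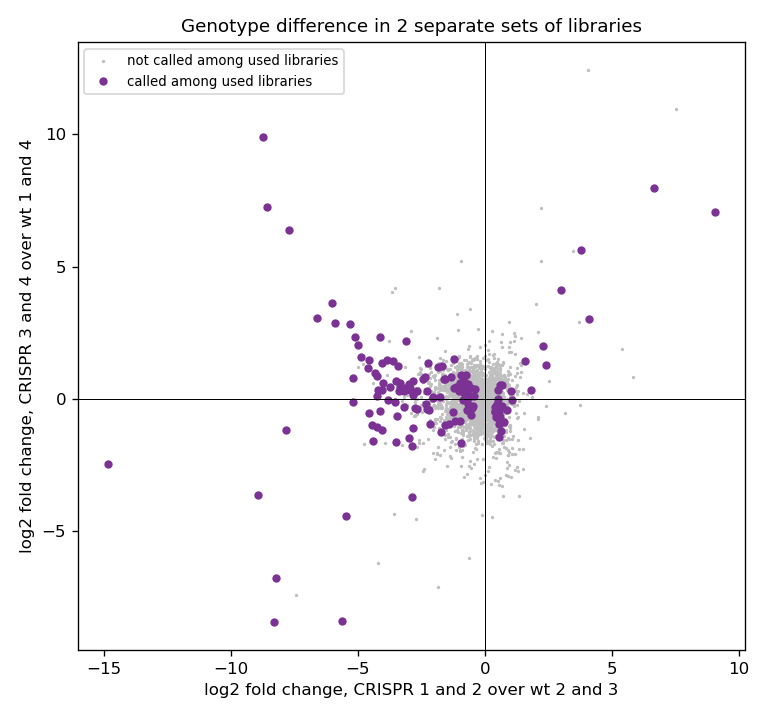
Each point is a gene, with its log2 change (CRISPR over wt) among the used libraries on the x axis (CRISPR 1 and CRISPR 2 over wt 2 and wt 3) and among the not-used libraries on the y axis (CRISPR 3 and CRISPR 4 over wt 1 and wt 4), and purple marks the 151 genes called among the used libraries. The correlation across 9044 genes is 0.041, and 56 of the 151 marked genes have the same sign on both axes.

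The last comparison asked how not-used libraries differed from used ones at a fixed genotype. The edgeR test called 0 of 9255 genes (1402 at an unadjusted p under 0.05), DESeq2 called 171 and edgeR with no filter 1. NijA, a Ninjurin cell adhesion gene, had a log2 difference of 0.63 (not used over used, SE 0.14, adjusted p = 0.291), and Dph1, of diphthamide synthesis, of -0.56 (SE 0.089, adjusted p = 0.291), the smallest p-values in their directions, which did not pass.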

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

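In this part the tests of tissue, genotype, library spread, strain background and stage were chosen only after the result was seen. The counts over all splits and the length test were not. The limit to splits that part every numbered pair was no part of the rule set beforehand.

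Over 180 groups of 4 libraries, 16 (8.89%) held a library whose gap to the nearest other was unusually large for the group's range. Chance gives about 1 in 20 for independent, normally distributed values. Many of the genes were named for differences between these same libraries and the lists share genes, so the share cannot be read against that rate. Of the 16, 6 were in CRISPR 3, where Jon65Aiv reached 613 CPM, Jon25Bi 115.4 CPM, CG17145 68.9 CPM, Fbp1 21.0 CPM, CG8661 20.8 CPM and alphaTry 14.4 CPM, while the other CRISPR libraries lay at or below 4.65, 0.965, 0.127, 4.30, 0.0920 and 0.0508 CPM. The wt 1 library was far from the other wt libraries in 5 values, namely Antdh at 11.996 CPM (others 5.00 to 5.91) and the mean log2 CPM of proliferation genes at 7.54 (others up to 7.20), ribosome biogenesis genes at 7.85 (others up to 7.41), ecdysone response genes at 4.47 (others from 5.48) and other-disc genes at 2.65 (others from 3.19). The wt 4 library stood apart in the correlation with transcript length (-0.40, others from 0.19), GstT3 at 4.56 CPM (others up to 2.41), Eip75B at 271 CPM (others from 297) and the mean log2 CPM of extracellular matrix genes at 6.12 (others from 6.50). In CRISPR 1, y stood at 5.75 CPM against at most 1.07 in the other CRISPR libraries.

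The first pattern is the 164 genes that fell at least 8-fold among the used libraries, with the 96 genes that changed less. Against wt 1 and wt 4, CRISPR 1 and CRISPR 2 differed in the 164 genes by a median log2 of 0 (quartiles -0.19 and 0.071), against -2.41 with wt 2 and wt 3, all with an offset of 0.5 CPM that shrinks differences. With an offset of 0.05 CPM these were 0 (quartiles -0.60 and 0.36) and -4.50. With the offset of 0.5 CPM, CRISPR 2 against wt 4, which share no number with each other, gave 0 (quartiles -0.31 and 0.14). Together these values argue against genotype as the cause for the 164 genes as a set. Single genes may differ, since 12 of the 264 genes called among the used libraries were also called over all 8. Not all of these 12 are among the 164, as CG7173, CG12592 and sordd2 rose. The fit to all 8 also holds the used libraries, so the overlap is not independent. Tissue other than wing disc in wt 2, wt 3 and CRISPR 3, led by Jon65Aiv at 1267, 1282 and 613 CPM, is a candidate source that stays open. Of the 164, 44.5% were at least 2-fold higher in CRISPR 3 than in CRISPR 1 and CRISPR 2 (1.29% of uncalled genes), where over 50% was asked. Without an offset of 0.5 CPM the share was 73.8% (64.8% over all that fell, seen before that bound was set). The bound asks about CRISPR 3 alone, so it cannot decide whether wt 2 and wt 3 held such tissue. In 118 of the 164 (72.0%), wt 1 and wt 4 were both over 8-fold below wt 2, a library that chose the genes. For the 96 genes, CRISPR 3 and CRISPR 4 against wt 1 and wt 4 gave a median log2 of -0.15 in the called direction (quartiles -0.54 and 0.28, 35.4% in that direction) against 0.87 among the used libraries, and CRISPR 1 and CRISPR 2, which chose the genes, gave 0.55 (85.4%) against wt 1 and wt 4, so that genotype cannot be told apart from differences between libraries. Medians for CRISPR 3 or CRISPR 4 against wt 1 or wt 4 singly ran from -0.59 to 0.13. The wt 1 and wt 4 libraries themselves differed by a median of 0.66 in these genes, which keeps genotype open. So does the sharing of numbers 1 and 3 between the sets, since pairing, as far as it holds, pulls their changes apart. The number of calls depended on the spread used, since with the spread over all 8 libraries and the same genes tested 5 of the 264 were left. That fit also takes in the spread among the not-used libraries, so it cannot single out the closeness of wt 2 and wt 3.

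The second pattern is the 17 genes called over all 8 libraries. Of the 35 splits of the libraries into 4 and 4, 1 gave as many calls, the real one, and the highest other gave 5. That was reached by 2 splits, wt 1, CRISPR 1, wt 2 and wt 3 against the rest, and wt 1, CRISPR 1, wt 4 and CRISPR 4 against the rest, which keeps every numbered pair whole, but most of these splits leave numbered pairs whole. Of the 8 splits that part all 4 pairs, as the real one does, the highest other gave 0, and 8 are too few for a share under 0.05. Chance therefore stays open. The rule set beforehand asked for a share under 0.05 of all 35 splits, which 1 of 35 meets, and did not limit the splits by pairs. A strain background that differs around single loci is a candidate explanation, since 4 of the 17 lie within 100000 bp of another (random draws give 0.631 on average, one-sided permutation p = 0.0336). These are adjacent pairs, sordd2 with CR44383 and lncRNA:CR44185 with lncRNA:CR44186, which may each be a single locus. Genotype stays open beside it, because the control cross differs from the CRISPR cross in its background too.

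The third pattern is the distance of wt 4 and CRISPR 4 from the other libraries. Over 6264 genes their spread against the other 6 was 1.90 times the spread among those 6, and 1.46 times after each library's trend with transcript length was removed (1.77 and 1.38 without wt 3), which argues against the length trend as the whole cause. Developmental stage stays open. The median absolute log2 difference of 19 ecdysone response genes was 0.74 against 0.18 in random lists, at percentile 100 of 10000 such lists. Those lists were matched on mean expression but not on how far genes vary between libraries, so the percentile cannot decide it. The mean log2 CPM of the whole ecdysone list was 5.58 in wt 4, 5.56 in CRISPR 4 and 5.57 in CRISPR 3, and lowest in wt 1 (4.47). It was 5.48 in wt 2 and in wt 3, 4.97 in CRISPR 1 and 4.98 in CRISPR 2. This mean therefore does not set wt 4 and CRISPR 4 apart from wt 2, wt 3 and CRISPR 3. The labels give no stage finer than wandering larvae and no batch, and as the pair holds 1 library of each genotype, no effect of genotype was tested for it.

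For the use of libraries, the real split gave 0 calls in edgeR (1402 at an unadjusted p under 0.05, 171 in DESeq2) and the highest other 3. All 34 splits that could be fitted beside genotype reach 0 by necessity, so their count says nothing about chance.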

How the results depend on the processing

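The fits that took the spread over all 8 libraries with the same genes, added the block to the interaction, summed wt 2 and wt 3, exchanged library arms or omitted several libraries were chosen after seeing the data. The 31 named genes called among the used libraries kept direction and call in 407 values under the alternatives, lost the call in 159 and reversed in 7, and the 8 called over all 8 kept both in 120 and lost the call in 88. Causes were not tested. Genes with few reads, such as lab and abd-A, are limited by depth.

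Among the used libraries 264 calls became 400 with no filter, 787 with DESeq2, 398 with limma-voom, 780 at an adjusted p under 0.1, 4 with the spread over all 8 libraries (5 with the same genes), 40 with wt 2 and wt 3 summed, 0 with wt 1 and wt 4 as the wt arm (224 at an unadjusted p under 0.05 in edgeR), and 39 (without wt 2) to 5759 (without CRISPR 2) when 1 library was left out, with 42 without wt 3 and 5056 without CRISPR 1, where a lone library was assumed to vary like the other arm. CRISPR 3 and CRISPR 4 as the CRISPR arm gave 369 calls, 81 of them shared with the 264. Over all 8 libraries 17 calls became 122 with DESeq2, 68 with limma-voom and library weights, 7 with use status as a term, 8 in the not-used libraries alone, 2 with wt 2 and wt 3 summed, and 1 to 26 when 1 library was left out. Omitting wt 2, wt 3 and CRISPR 3, or wt 4 and CRISPR 4, or wt 2, wt 3, CRISPR 2 and CRISPR 3 left 0 (123, 433 and 105 at an unadjusted p under 0.05 in edgeR). The interaction's 0 calls became 67 with no filter and 151 with DESeq2, and those of use status 1 and 171. With an estimated correlation 0 lists passed in either comparison.

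The replicate number as a block called 14 genes over all 8 libraries, 10 shared with the 17, and moved the lists passing camera from 2 to 5. Besides GstT3 it changed no call of a gene named by the rule, while 7 genes named outside it lost theirs. No paired analysis was possible for the used libraries because the genotypes share only number 2 there.

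For Antp among the used libraries DESeq2 gave 0.41 and leaving out 1 library 0.25 to 0.55, and the not-used libraries gave -0.11. With wt 1 and wt 4 as the wt arm the log2 change reversed for exd (-0.094), tio (0.20), Lsp1alpha (0.020), Jon65Aiv (3.22) and cpx (0.87). With CRISPR 3 and CRISPR 4 as the CRISPR arm it reversed for hth (0.44), lab (0.65), LamC (-1.04), Him (0.28), EcR (-0.39), Hr4 (2.01), stg (-0.20) and Polr1A (-0.13). Leaving out 1 used library gave -0.25 to 0.099 for hth and -2.42 to 0.57 for lab, and tsh was 0.014 with the spread over all 8 and 0.035 with the same genes. Over all 8 libraries exd was -0.19 in the not-used libraries, -0.020 with wt 2 and wt 3 summed, -0.099 without wt 2, wt 3 and CRISPR 3, -0.028 without these and CRISPR 2, and -0.033 to 0.15 when 1 library was left out. There lab was -0.14 with limma-voom, -0.058 with library weights, -0.24 without wt 2, wt 3 and CRISPR 3, and -0.15 to 0.56 when 1 was left out, tio ran from -0.23 to 0.083, and cpx was 0.40 without wt 2, wt 3 and CRISPR 3. Camera's direction reversed for tracheal cells with use status as a term (adjusted p = 0.897) and with the block (0.800), and for other discs without genes held by several lists (0.793). The reversed values passed the threshold only for LamC and Hr4 in the exchanged CRISPR arm and for hth without CRISPR 1.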

Other observations

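Among genes that passed among the used libraries but not over all 8, or in neither, some still lay on one side of every control library, noticed after their values were seen. The heat shock gene Hsp70Ba stood at 133, 54.2, 9.23 and 74.6 CPM in CRISPR 1 to CRISPR 4 and at 3.26 to 7.13 CPM in the wt libraries, and its count is uncertain because of near-identical copies. The glutathione S-transferase gene GstT3 ranged from 6.74 to 10.5 CPM in CRISPR and from 2.22 to 4.56 CPM in wt, and Gpo1 from 3.47 to 8.38 CPM and from 0.975 to 2.17 CPM. The nuclear receptor gene Eip75B ranged from 332 to 435 CPM in CRISPR and from 271 to 300 CPM in wt. The muscle regulator lms, at low levels and overlapping Mgat1, ranged from 0.437 to 0.813 CPM in CRISPR and from 0.873 to 3.28 CPM in wt. Of the 264 genes called among the used libraries, 28 (11 that rose and 17 that fell) separated the genotypes over all 8, a number that is not independent because 4 of the 8 libraries chose the genes and chance gives 2.86% of genes in general.

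The transgene marker y stood at 5.75, 1.07, 0.495 and 0.391 CPM in CRISPR 1 to CRISPR 4 and at 0.0660 to 0.125 CPM in wt, with 7 reads in all in wt 2 and wt 3. In the marker list (4 tested members, too few for camera) 0 were called by edgeR in either comparison (2 and 1 at an unadjusted p under 0.05, 2 and 1 in DESeq2, 0 and 0 in limma-voom), and y passed adjusted over the list alone in both. Among the used libraries w passed there too, in the other direction, from 685 ± 1.16 CPM in wt to 365 ± 105 CPM in CRISPR (log2 -0.95, adjusted p = 0.0864 over all genes), with 87.1 CPM in wt 1 and 121 CPM in CRISPR 3.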
